A study of Rattus norvegicus with 15 samples.

How the data were processed

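RNA from the subfornical organ of male Sprague Dawley rats aged 10 to 12 weeks was measured on 15 Affymetrix rat expression arrays, 5 for each of 3 groups (control, water deprivation and food deprivation). Each array carried RNA pooled from 5 animals, so that 25 animals stand behind each group and the 5 arrays of a group are independent pools. Per the labels, tissue was kept in RNAlater, homogenised in QIAzol, purified on RNeasy MinElute columns and amplified and labelled with biotin by a MessageAmp II kit. The labels give 48 h of food deprivation for the food-deprived samples and no treatment protocol for the control and water-deprived samples. The series design text, read literally, describes denial of food for 48 h in every condition. The length of water deprivation and the batch in which each array was processed are not given in the sources used here.

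The deposited values are signal intensity per probe set on a linear scale, made by the authors with GCOS 1.2 per the submitters' processing notes, which do not state the role of the program or the scaling target. Tested on the table itself, every array has the same trimmed mean of 100.0 (2% trimmed at each end) while its quantiles differ, so the authors scaled each array and did not equalise the distributions. The deposited table was therefore used without further normalization, as log2(signal + 16). Detection calls and raw probe intensities were not used. Arrays give no counts, so no counting interval applies and the number of arrays limits the precision.

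The table holds 31099 probe sets, of which 57 are controls. The annotation supplied with the table assigns 1 gene symbol to 20832 probe sets, several symbols to 436 and none to 9780. Of those with 1 symbol, 20764 have a gene identifier that is present in the RefSeq gene table. Gene coordinates were not used. A probe set was tested when its mean over the 15 arrays exceeded the 30th percentile of such means, a log2 value of 5.11, which left 21729 probe sets and 11510 genes. A gene is represented by its probe set with the highest mean over all 15 arrays among those assigned to that gene alone.

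Tests used R 4.3.3 and limma 3.58.1. The 3 groups were fitted together by group means with 12 residual degrees of freedom, and the 3 pairwise contrasts were tested, two-sided, by moderated statistics with a trend of the variance on the mean. Adjusted p values are Benjamini-Hochberg values over all probe sets tested within a comparison, with a threshold of 0.05 and no minimum fold. A moderated F test covered any difference among the 3 groups. Differences are given as log2 fold changes with the standard error (SE) of the limma fit. Gene lists were tested by camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Of 31 lists, 30 had at least 5 measured members. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

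The groups, comparisons, gene lists, tests, filter, rule for naming genes and main alternatives were fixed before the data were examined. The rule names, per comparison, up to 10 genes with the largest increase and 10 with the largest decrease among those that passed the test with every array of the first group on the same side of the mean of the second. Unnamed transcripts are skipped, and where no gene passed in a direction the 5 with the smallest unadjusted p are named. It adds up to 4 members of each list that passed or held a member that passed, and a fixed set of genes of fluid and energy balance. Of that set, Fosb, Agtr1b, Npr3, Avpr1a, Pomc, Trpv1 and Nos1 were below the filter on dim probe sets and Rxfp1 had no probe set of its own, so they have no test.

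Control probe sets for the 5′ and 3′ ends of Actb and Gapdh showed that the arrays fall into a set with a high and a set with a low 5′/3′ signal ratio, a measure of RNA integrity and amplification length. The split at a mean log2 ratio of -1 was chosen after seeing the data. It was added to the fit as a term, which leaves 11 residual degrees of freedom. In that fit the difference between water deprivation and control rests on the 8 low arrays, that between water and food deprivation on the 7 high arrays, and that between food deprivation and control on both together.

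The alternatives fixed in advance were quantile normalization, median centring, offsets of 1 and 64, no filter, a filter at the 50th percentile, a variance without a trend, array weights, a fit of only the 10 arrays compared, a minimum of 1.5-fold, the replicate number as a block, and leaving out each array. Alternatives added after seeing the data used the array set or the 5′/3′ ratio, alone or with another change. For each comparison, 100 of the 126 splits of its 10 arrays into groups of 5 were fitted. The share that the common controls give to both comparisons against control was simulated 100 times. The fits were tested on simulated data of 21729 probe sets. Without the array set term, 24 of 67 simulated changes of 0.5 (35.8%), 59 of 67 of 1 (88.1%) and 64 of 66 of 2 (97.0%) on the log2 scale were found between water deprivation and control, with 5 calls among unchanged probe sets. With an effect of the array set added to unchanged groups, 1371 unchanged probe sets were called between food deprivation and control. With the term, 4 were, and 1 of 67 (1.49%), 25 of 67 (37.3%) and 57 of 66 (86.4%) simulated changes were found. The simulated spread was that within each group and array set, and the changed probe sets carried no set effect. In the real fit without the term, the set difference adds to the spread of the water-deprived arrays. The shares found without the term can therefore be too high for the real data.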

Results

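The subfornical organ is a small sensory structure of the brain outside the blood-brain barrier, whose neurons respond to angiotensin II, to sodium and osmolality, and to hormones of energy balance. Its transcriptome was measured in 3 groups of rats, control, water-deprived and food-deprived, with 5 arrays per group and 5 pooled animals per array. Correlations between arrays ranged from 0.835 to 0.981 across probe sets, and the first and second principal components held 38.0% and 22.2% of the variance.

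The control probe sets of Actb and Gapdh divided the arrays into a high and a low set by their 5′/3′ signal ratio, a division chosen after seeing the data. All 5 food-deprived arrays and water-deprived arrays 1 and 2 formed the high set of 7, with mean log2 ratios from -0.86 to -0.71. The 5 controls (-1.67 to -1.24) and water-deprived arrays 3 to 5 (-2.81 to -1.28) formed the low set of 8. The 25th percentile of the signal was 15.7 to 17.4 in the high set and 12.4 to 14.2 in the low set. No set holds both control and food-deprived arrays, so each set gives no value of its own for that comparison, and the fit with the array set as a term reaches it through the water-deprived arrays. In that fit 3461 probe sets differed between the sets at a limma adjusted p below the threshold, 2062 higher and 1399 lower in the high set. This set difference is estimated only from water-deprived arrays 1 and 2 against 3 to 5, because the other groups lie within a single set. It includes water-deprived array 3, which had the lowest ratio (-2.81).

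**Figure D1:**
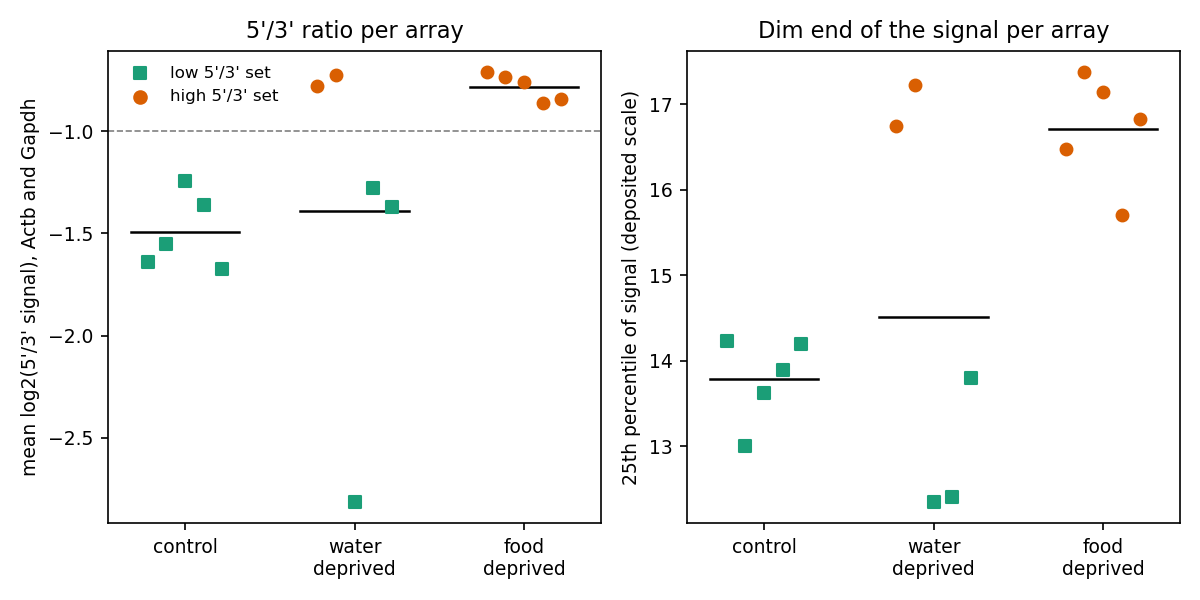
Mean log2 5′/3′ signal ratio of the Actb and Gapdh control probe sets (left) and 25th percentile of the deposited signal (right) for each of the 15 arrays, with circles for the high set, squares for the low set, bars for group means and a dashed line at -1. The 5 food-deprived arrays and 2 water-deprived arrays lie above -1, and the 5 controls and 3 water-deprived arrays below it.

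Water deprivation was compared with control to find transcripts of the organ that differ when rats lack water. Bpifa1, which encodes a secreted lipid-binding protein, rose 2.02-fold (log2 difference 1.01, SE 0.13, 5 arrays against 5, limma adjusted p = 0.0130), and its 5 water-deprived arrays all lay above the highest control. Its probe set is dim, with a control mean log2 value of 5.26 against the filter at 5.11. With the filter at the 50th percentile limma called 0 probe sets in this comparison. Bdnf and Vgf lay above the control mean in 5 of 5 arrays without passing the adjusted test. For Vgf, 3 of the 5 arrays lay above the highest control. Bdnf, a neurotrophin whose gene responds to neuronal activity, was at 3.60-fold (log2 1.85, SE 0.38, adjusted p = 0.386), although its other probe set gave 0.36. Vgf, the precursor of several secreted neuropeptides, was at 2.46-fold (log2 1.30, SE 0.33, adjusted p = 0.523).

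When the array set was added as a term, which leaves the 3 low water-deprived arrays against the 5 low controls, 5 named genes and 1 unnamed probe set (log2 1.23, SE 0.17) rose. Vgf was 3.72-fold higher (log2 1.89, SE 0.24, adjusted p = 0.0148). The calcium-sensing receptor gene Casr was 2.55-fold higher (log2 1.35, SE 0.20, adjusted p = 0.0227). Fxyd2, a regulatory subunit of the sodium pump, was 2.27-fold higher (log2 1.18, SE 0.16, adjusted p = 0.0148) and Bpifa1 2.08-fold (log2 1.05, SE 0.14, adjusted p = 0.0148). Ercc1, a subunit of a DNA repair endonuclease, was 1.75-fold higher (log2 0.80, SE 0.11, adjusted p = 0.0148). Each of these genes was above the highest control in 3 of 3 low arrays. In the high set, 2 water-deprived against 5 food-deprived arrays, they differed by 1.14 (SE 0.27) for Vgf, 0.53 (SE 0.23) for Casr, 0.53 (SE 0.19) for Fxyd2, 0.88 (SE 0.17) for Bpifa1 and 0.05 (SE 0.12) for Ercc1. Without the array set term Casr (0.94), Fxyd2 (0.78) and Ercc1 (0.42) had adjusted p values of 0.585, 0.639 and 0.752.

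**Figure D2:**
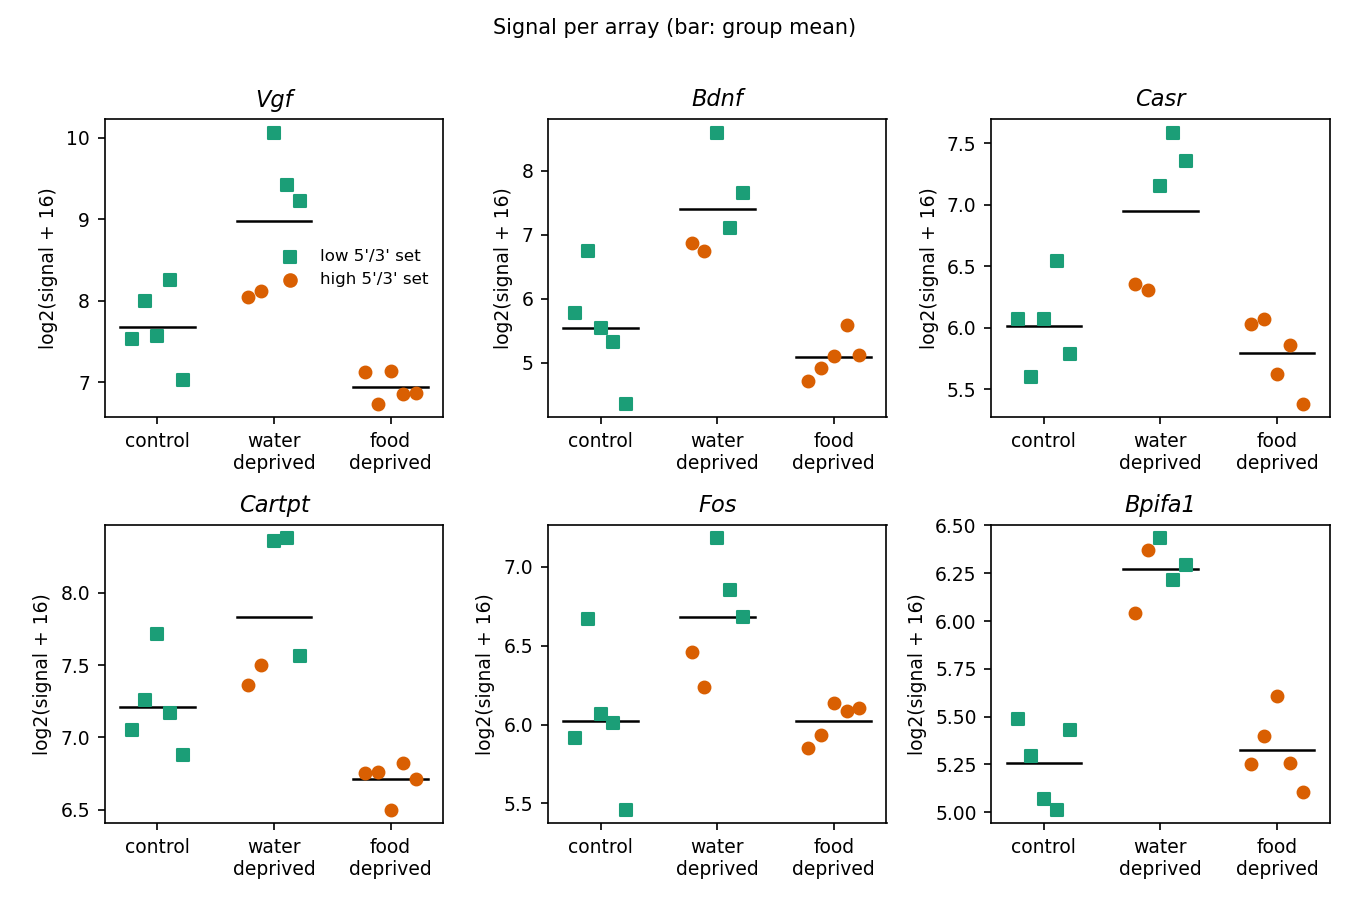
Log2(signal + 16) of Vgf, Bdnf, Casr, Cartpt, Fos and Bpifa1 on each array by group, with circles for the high and squares for the low 5′/3′ set and bars for group means. Vgf lies between 9.22 and 10.06 on the 3 low water-deprived arrays, 8.04 and 8.12 on the 2 high ones, 7.02 and 8.25 in controls and 6.73 and 7.14 in food deprivation.

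Immediate early genes, the first to be transcribed in activated neurons, leaned upward in water deprivation. Of 20 measured, 18 lay above 0 (median log2 0.12, adjusted p = 0.00345; adjusted p = 0.0596 with an estimated correlation). In limma 0 members passed over all genes and 0 when adjusted over the list alone. Fos was at 1.58-fold (log2 0.66, SE 0.20, adjusted p = 0.672), Egr1 at 0.55 (0.32 without water-deprived array 3), Dusp1 at 0.44 and Klf4 at 0.33, while Junb (0.07) and Nr4a1 (0.19) were closer to control. Adding the array set term left 14 of 20 above 0 (median 0.10, adjusted p = 0.00268), with an adjusted p = 0.0488 with an estimated correlation. Dusp1 was then at 0.86 (adjusted p = 0.0989) and Fos at 0.88 (adjusted p = 0.316), both past the test when adjusted over the list alone, while Nr4a1 was at 0.014 and Junb turned to -0.10. In the same fit neuron markers lay above 0 in 24 of 32 (median 0.16, adjusted p = 0.000171; adjusted p = 0.656 with an estimated correlation) and oligodendrocyte markers below 0 in 21 of 22 (median -0.33, adjusted p = 0.00268; adjusted p = 0.656 with an estimated correlation).

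Genes of appetite and energy balance signalling also leaned upward, with 28 of 39 above 0 (median 0.15, adjusted p = 0.0101) and an adjusted p = 0.0596 with an estimated correlation. No member passed over all genes in limma and 2 passed when adjusted over the list alone, Bdnf and Grp, the gene of gastrin-releasing peptide (0.72, SE 0.18). Cartpt, the precursor of the CART peptide, was at 0.62, and Sstr2, a somatostatin receptor (0.43), Adipor2 (0.41), Lepr (0.32), Ghsr (0.28), Npy (0.16), Insr (0.13) and Adipor1 (0.05) differed by less than 1.5-fold. With 1 array left out Adipor2 ranged from 0.20 to 0.74, Lepr from 0.016 to 0.69 and Insr from -0.020 to 0.29. In the fit with the array set 24 of 39 lay above 0 (median 0.05, adjusted p = 0.00525; 0.0486 with an estimated correlation), beside the neuron marker median of 0.16. Cartpt was then at 0.89, Bdnf at 2.24 and Lepr at 0.13, and Adipor2 (-0.12), Insr (-0.11) and Adipor1 (-0.012) turned direction. These directions depend on single arrays. With 1 array left out of that fit Lepr ranged from -0.22 to 0.56, Adipor2 from -0.36 to 0.26, Insr from -0.32 to 0.073 and Adipor1 from -0.13 to 0.16. Cartpt (0.75 to 1.16) and Bdnf (1.83 to 2.58) stayed above control.

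Glucocorticoid response genes lay above 0 in 24 of 31 (median 0.15, adjusted p = 0.00338; adjusted p = 0.0596 with an estimated correlation), among them Sult1a1 (0.88), Nfkbia (0.50), Angptl4 (0.44) and Fkbp5 (0.37, or 0.15 without water-deprived array 3). In limma 0 members passed over all genes and 0 when adjusted over the list alone. With the array set term 24 of 31 lay above 0 (median 0.13, adjusted p = 0.000313, or 0.0486 with an estimated correlation), beside the same marker shifts. Sult1a1 was at 0.86, Nfkbia at 0.30, Angptl4 at 0.47 and Fkbp5 at 0.49. With 1 array left out of that fit they ranged from 0.56 to 1.12, 0.12 to 0.48, 0.39 to 0.59 and 0.11 to 0.69. Genes of energy production and protein turnover were shifted by small amounts without the term. Of the oxidative phosphorylation genes, 74 of 76 lay above 0 (median 0.17, adjusted p = 1.35e-12), for example Atp5if1 (0.37) and Ndufb5 (0.31), beside choroid plexus markers above 0 in 23 of 26 (median 0.42, adjusted p = 0.0805). Proteasome genes lay above 0 in 28 of 36 (adjusted p = 7.69e-06), with Psmb2 at 0.43 and Psmc3 at 0.23, and ribosomal protein genes in 35 of 44 (adjusted p = 5.98e-05), with Rpl7 at 0.20 and Rps9 at 0.22. With an estimated correlation these lists had an adjusted p = 0.612, 0.0603 and 0.694. No member passed over all genes, and adjusted over the list alone 1 did, Psmb2. Their medians with the array set term were 0.06, 0.10 and 0.02, with adjusted p values of 0.00525, 0.000192 and 0.633, and with an estimated correlation they were 0.656, 0.116 and 0.925.

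Microglia and macrophage markers leaned downward, with 19 of 23 below 0 (median -0.20, adjusted p = 9.54e-05; adjusted p = 0.381 with an estimated correlation). Tyrobp was at -0.46, Aif1 at -0.44 (another probe set 0.071), Fcer1g at -0.40 and the fractalkine receptor gene Cx3cr1 at -0.38, and 0 members passed by either adjustment. In the fit with the array set 21 of 23 lay below 0 (median -0.24, adjusted p = 1.21e-05; adjusted p = 0.206 with an estimated correlation), with Tyrobp at -0.26 and Aif1 at -0.49, beside the oligodendrocyte marker median of -0.33.

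The genes of thirst and salt appetite signalling did not pass as a list without the array set term, where 13 of 23 lay above 0 (adjusted p = 0.42). With it 14 of 23 did (median 0.09, mean 0.24, adjusted p = 0.00654), with an adjusted p = 0.116 with an estimated correlation. Beside Casr, which passed over all genes, the calcitonin receptor gene Calcr was at 1.01 (SE 0.18; another probe set 0.22), the natriuretic peptide receptor gene Npr1 at 0.95 (SE 0.18) and Agtr1a, a receptor of angiotensin II, at 1.23 (SE 0.32; another probe set 0.61), with adjusted p values of 0.127, 0.149 and 0.499. Adjusted over the list alone 4 were higher and 1 was lower, beside the neuron marker median of 0.16 in this fit. Without the term Calcr was at 0.63, Npr1 at 0.54 and Agtr1a at 0.74. Avp (-0.65, SE 0.69), Oxt (-0.75, SE 0.71), Agt (0.03), Scn7a (-0.21), Sgk1 (0.36), Slc5a3 (0.24), Slc6a6 (-0.35) and Ttr (0.01) were within 3 SE of control. With 1 array left out Avp ranged from -1.17 to -0.18, Oxt from -1.32 to -0.15 and Sgk1 from 0.14 to 0.61. Agt then ranged from -0.28 to 0.25, Scn7a from -0.42 to -0.013 and Slc5a3 from -0.0010 to 0.53. For Slc6a6 the range was -0.46 to -0.21 and for Ttr -0.15 to 0.24. The term turned Avp (0.56), Oxt (0.46), Scn7a (0.11), Slc5a3 (-0.047) and Ttr (-0.35) to the opposite sign, and none passed over all genes. With 1 array left out of that fit Avp ranged from 0.13 to 1.13, Oxt from -0.075 to 1.12 and Scn7a from -0.10 to 0.31. Slc5a3 ranged from -0.43 to 0.40 and Ttr from -0.52 to -0.077.

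In limma 1 probe set passed as higher and 0 as lower between water deprivation and control, while 1412 had an unadjusted p under 0.05, against 1086 expected by chance (616 higher, 796 lower). The 5 lower genes with the smallest unadjusted p failed the adjusted test: Dnmt3a, a DNA methyltransferase (-1.03, SE 0.19, adjusted p = 0.257), G0s2 (-0.75), Pogk (-0.54), Col2a1 (-0.53) and the cyclin gene Ccnd1 (-0.37), the last of which passed when adjusted over the cell division list alone. G0s2 passed without water-deprived array 3 (-0.90, adjusted p = 0.00511) and Dnmt3a without water-deprived array 5 (-1.18, adjusted p = 0.0388). The call for Bpifa1 was lost, and 0 probe sets were higher, without water-deprived array 2, control 3 or control 4. The 6 calls with the array set as a term became 0 without water-deprived array 3 (Vgf 1.65, adjusted p = 0.0930) or control 3, 1 without water-deprived array 4, 3 without control 1, and 12 without control 4. They also became 0 in a limma fit of the low arrays alone, which has the same log2 differences on fewer degrees of freedom (adjusted p = 0.307 for the 5 genes, 782 probe sets at an unadjusted p under 0.05), or with the replicate number as a block (1038).

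Food deprivation was compared with control to find transcripts that differ when rats lack food. Gosr1, a Golgi SNARE protein, was 15.1-fold higher (log2 3.91, SE 0.65, 5 arrays against 5, adjusted p = 0.00391) by its brightest probe set, but -0.16 and 0.37 by its other probe sets. The hormone genes Avp (vasopressin) and Oxt (oxytocin) were 8.79-fold and 8.68-fold lower (log2 -3.14, SE 0.69, and -3.12, SE 0.71), and Pmch, the precursor of melanin-concentrating hormone, 5.50-fold lower (log2 -2.46, SE 0.62). All food-deprived arrays are in the high and all controls in the low 5′/3′ set. These differences with the array set term were 0.23 for Gosr1, -0.10 for Avp, -0.10 for Oxt and -0.09 for Pmch, none of which passed.

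In limma 1037 probe sets (359 genes by their representative probe set) were higher and 817 (301 genes) lower in food deprivation, and 5715 had an unadjusted p under 0.05. The balance depends on the scaling, since 55.9% of the calls were higher as deposited, 45.7% after quantile normalization (815 higher, 970 lower) and 35.6% after median centring (652 higher, 1178 lower), which shifts the median of all probe sets by 0.10. When the array set was a term, 0 were higher and 0 lower by limma. The smallest adjusted p was then 0.339, and 1879 probe sets had an unadjusted p under 0.05. Of the 1854 calls, 1736 (93.6%) had the same direction in water-deprived arrays 1 and 2 against water-deprived arrays 3 to 5, which share the treatment and differ in array set. The differences correlated at 0.897 across these probe sets, which are not independent of one another.

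**Figure D3:**
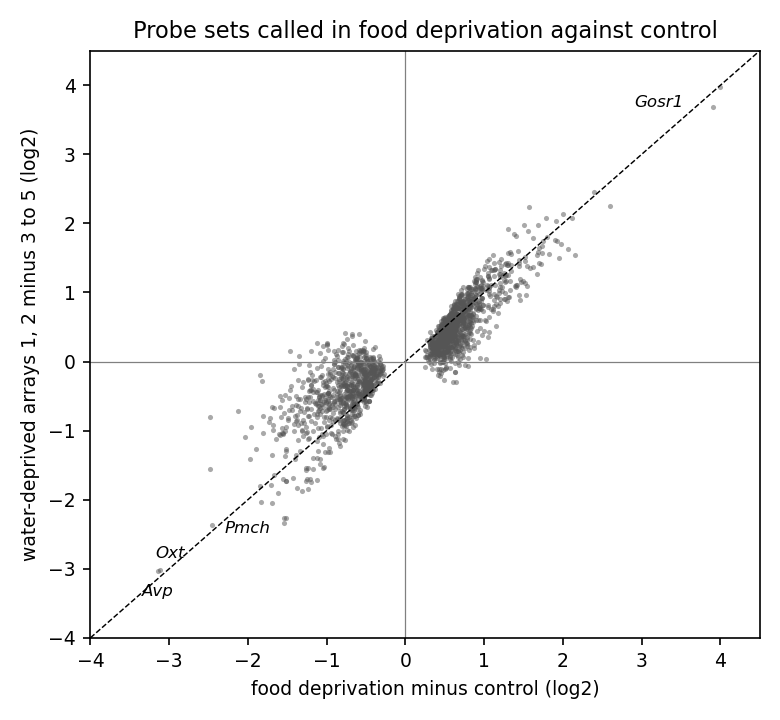
Each point is 1 of the 1854 probe sets called between food deprivation and control, with its log2 difference between food deprivation and control on the horizontal axis, the log2 difference between water-deprived arrays 1 and 2 (high set) and 3 to 5 (low set) on the vertical axis, and a dashed line of equality. Avp lies at -3.14 and -3.03, and 93.6% of the points have the same sign on both axes.

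The other genes with the largest increases were each higher in 5 of 5 arrays, as the rule for naming required. The values were 3.00-fold for Sbf2 (log2 1.59) and 2.92-fold for the transcription elongation factor gene Tcea1 (1.55). They were between 1.25 and 1.34 on the log2 scale for Rps27l, the co-chaperone gene Dnajb6, Snrpn, Rlig1, Tmem158, Strbp and Ranbp1. Adding the array set term turned Rps27l (-0.060), Rlig1 (-0.27), Tmem158 (-0.10) and Strbp (-0.14) to the opposite sign and left Sbf2 at 0.23, Tcea1 at 0.17, Dnajb6 at 0.17, Snrpn at 0.29 and Ranbp1 at 0.34. The largest decreases, in 5 of 5 arrays by the same rule, included Pnma8b (log2 -2.49, SE 0.36), the axonal motor gene Kif1a (-2.04), the cohesin loader gene Nipbl (-1.98), Sobp (-1.85), Vof16 (-1.81), the transcription factor gene Mga (-1.71) and Gnai2 (-1.71), an inhibitory G protein subunit. For Strbp and Nipbl another probe set passed in the opposite direction (-1.08 and 0.99), and other probe sets that did not pass were at -0.019 for Sbf2, 0.14 for Kif1a and -0.39 for Mga. In the fit with the array set, Pnma8b (-0.92), Kif1a (-0.94), Mga (-0.89), Vof16 (-0.78) and Nipbl (-0.56) were still lower in value without passing, and Gnai2 was at 0.08.

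**Figure D4:**
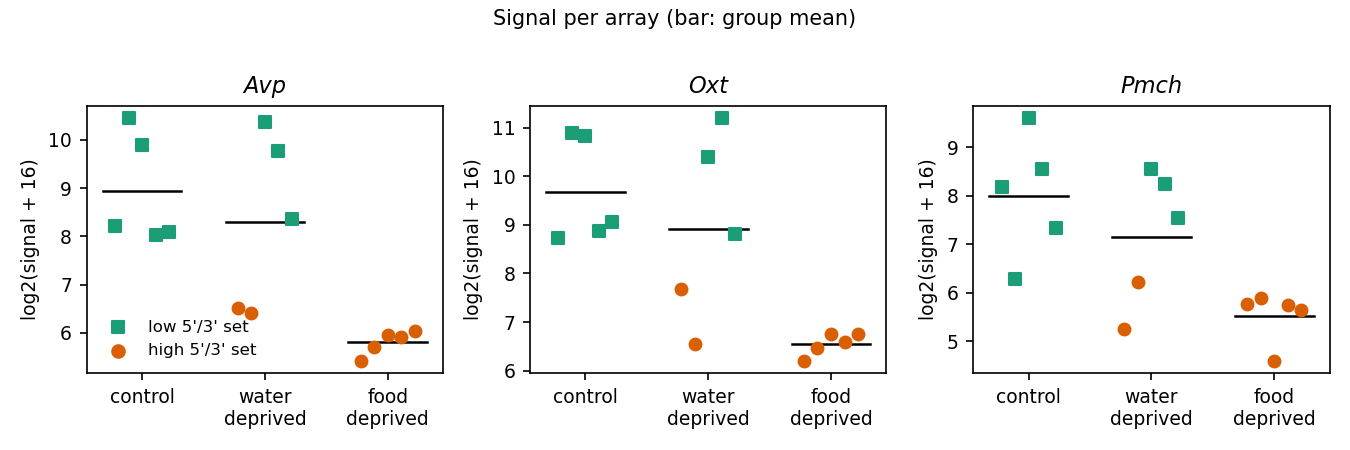
Log2(signal + 16) of Avp, Oxt and Pmch on each array by group, with circles for the high and squares for the low 5′/3′ set and bars for group means. Avp lies between 5.42 and 6.04 in food deprivation, at 6.42 and 6.52 on the 2 high water-deprived arrays, between 8.37 and 10.38 on the 3 low ones and between 8.03 and 10.46 in controls.

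Among genes of appetite and energy balance signalling 5 of 39 rose and 1, Pmch, fell, and the same numbers passed when adjusted over the list alone. The galanin receptor gene Galr2 was 1.76-fold higher (log2 0.82, SE 0.19, adjusted p = 0.0166), the somatostatin receptor genes Sstr2 and Sstr3 1.57-fold and 1.52-fold (0.65 and 0.60), the ghrelin receptor gene Ghsr 1.36-fold (0.44, SE 0.12, adjusted p = 0.041) and Adipor2 2.00-fold (1.00). Their values with the array set term were 0.60, 0.45, 0.14, 0.45 and -0.34. Other probe sets that did not pass were at -0.13 for Galr2 and 0.086 for Adipor2. The list as a whole did not pass (adjusted p = 0.702), and its median (0.00057) and mean (-0.0075) differ in sign. Bdnf (-0.46), Cartpt (-0.50), Npy (0.14), Lepr (-0.22), Insr (0.18) and Adipor1 (-0.15) did not pass, but another probe set of Insr did (0.60, SE 0.14, adjusted p = 0.0159). The term turned Bdnf to 0.52, Cartpt to 0.16 and Insr to -0.44, none of which passed.

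Glucocorticoid response genes leaned upward, 22 of 31 above 0 (median 0.18, adjusted p = 0.0412; adjusted p = 0.597 with an estimated correlation), and 6 rose over all genes and 6 when adjusted over the list alone. They included the metallothionein gene Mt2A (1.65-fold, log2 0.73, SE 0.15) and the sulfotransferase gene Sult1a1 (1.92-fold, 0.94, SE 0.26). Sgk1 was at 0.23 and Fkbp5 at 0.33, and another probe set of Fkbp5 passed (0.58, SE 0.13, adjusted p = 0.0147). With the array set term the list had an upward median of 0.26 (adjusted p = 0.00558, or 0.365 with an estimated correlation), with Mt2A at 0.41 and Sult1a1 at 0.90. In that fit the difference includes the one between the low water-deprived arrays and control, where the list median was 0.13 and Sult1a1 was at 0.86. Between food deprivation and control in the same fit, neuron markers had a median of 0.44 (29 of 32 above 0) and choroid plexus markers of -0.88 (24 of 26 below 0). Of the genes of fasting and fatty acid metabolism, Angptl4, an inhibitor of lipoprotein lipase, rose 1.74-fold (0.80, SE 0.13, adjusted p = 0.00333) and the transcription factor gene Foxo1 fell by 0.92. With the term they were at 0.85 (SE 0.22) and -0.17.

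Ribosomal protein genes lay above 0 in 39 of 44 (median 0.20, adjusted p = 1.56e-07; adjusted p = 0.720 with an estimated correlation), with 9 higher over all genes and 18 when adjusted over the list alone, for example Rpl7 (0.37), Rps9 (0.34) and Rpl5 (0.32). Oligodendrocyte markers lay above 0 in 20 of 22 (median 0.51, adjusted p = 0.0130; adjusted p = 0.915 with an estimated correlation), among them the myelin genes Mbp (0.66, other probe sets -0.16 and 2.38), Cldn11 (0.65) and Gsn (0.27), with 0 members past the test by either adjustment. Genes of cholesterol and lipid synthesis lay below 0 in 25 of 33 (median -0.10, adjusted p = 0.0146; adjusted p = 0.720 with an estimated correlation), among them Dhcr7 (-0.56), Elovl6 (-0.53) and Srebf1 (-0.39, another probe set 0.35), with 0 members past the test by either adjustment. These lists differ in array set as all others in this comparison do, and with the term their medians were -0.026, -0.012 and -0.084, of which the last passed (adjusted p = 0.045; 0.526 with an estimated correlation), beside the same neuron and choroid plexus shifts.

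Single members of other lists passed between food deprivation and control, with the arrays of each group in different array sets. The glucose transporter gene Slc2a1 (0.51) and the urea transporter gene Slc14a2 (0.59) rose and Nfat5, the transcription factor of the hypertonic response, fell by 0.68. Of inflammation genes Ptges rose (0.75) and Stat3 fell by 1.33 (SE 0.20), and of clock genes Rorb (-0.60) and Rora (-0.80) fell, although another probe set of Rora passed at 1.06. Of the chaperone genes Calr (-1.24) and Syvn1 (-0.55) fell. Cell type markers that rose were Glul (0.51) and Mlc1 (0.52) of astrocytes, Cldn5 (0.64) of endothelium, Acta2 (0.56) and Notch3 (0.42) of mural cells, Cacng4 (0.50) of oligodendrocyte precursors and Ccn3 (0.56) of the neighbouring brain regions. Those that fell were Atp1b2 (-1.26) of astrocytes, Sparc (-0.67) and Col1a2 (-0.80) of the meninges, Ak7 (-0.74) of ependyma and Sv2b (-0.98) of neurons. Receptor and channel genes that rose were Grin2b (0.65), Gabrg1 (0.58), Scn4b (0.47) and Scnn1b (0.46). Cox5a (1.06), Atp5if1 (0.36), Psmd4 (0.41) and Psmc6 (0.57) rose and Psmb10 (-0.33) fell. Other probe sets that did not pass were at -0.10 and 0.29 for Slc14a2, 0.51 for Sv2b, 0.11 and -0.042 for Psmc6, 0.050 for Ptges and 0.14 for Grin2b. In the fit with the array set, Mlc1 (0.60), Cldn5 (0.93), Rora (-0.81), Rorb (-0.58), Psmb10 (-0.36), Sv2b (-0.61) and Stat3 (-0.66) did not pass, and Atp1b2 was at 0.29, Psmc6 at -0.10, Ccn3 at -0.046 and Acta2 at 0.032.

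Genes of the fluid balance signals other than Avp and Oxt did not pass in food deprivation, among them Agtr1a (0.06), Npr1 (0.16), Casr (-0.22), Agt (-0.26) and Scn7a (-0.04). Calcr was at -0.04 by its representative probe set, and another probe set passed at 0.80. Fos (-0.0020), Egr1 (0.28), Junb (0.08), Nr4a1 (0.13), Slc5a3 (-0.33), Slc6a6 (-0.50) and Ttr (0.49) did not pass either. Many of these turned direction with the term, with Casr at 0.82, Calcr at 0.90, Scn7a at 0.76, Agt at 0.53, Fos at 0.56, Slc6a6 at 0.25, Junb at -0.33, Nr4a1 at -0.30 and Ttr at -0.42, none of which passed. Without food-deprived array 1, 2, 3, 4 or 5 in turn 481, 408, 410, 540 and 558 probe sets were higher and 534, 468, 448, 476 and 596 lower. Without control 1, 3, 4 or 5 in turn 398, 492, 671 and 521 were higher and 409, 496, 611 and 570 lower, and without water-deprived array 3, which had the lowest 5′/3′ ratio, 1715 were higher.

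Water deprivation was compared with food deprivation to separate the deprivations from each other. Bdnf was 4.95-fold higher in water deprivation (log2 2.31, SE 0.38, 5 arrays against 5, adjusted p = 0.0301), although its other probe set gave 0.12. Vgf was 4.08-fold higher (2.03, SE 0.33, adjusted p = 0.0301), Cartpt 2.18-fold (1.12, SE 0.20, adjusted p = 0.0459) and Grp 2.13-fold (1.09, SE 0.18, adjusted p = 0.0301). The secretin receptor gene Sctr was 1.92-fold higher (0.94, SE 0.18, adjusted p = 0.0481) and Bpifa1 1.93-fold (0.95, SE 0.13, adjusted p = 0.0245). The others were Mga (1.26), Arid5b (1.12), the splicing factor gene Srrm2 (0.98) and the microtubule-binding gene Camsap2 (0.50). All 10 were higher in 5 of 5 arrays, as the rule for naming required. Other probe sets that did not pass were at 0.21 for Mga, 0.20 for Srrm2 and -0.22 for Camsap2.

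Within the high 5′/3′ set, where the array sets do not differ, the 2 water-deprived arrays exceeded the 5 food-deprived arrays by 1.72 (SE 0.47) for Bdnf, 1.14 (SE 0.27) for Vgf, 0.72 (SE 0.22) for Cartpt, 1.12 (SE 0.24) for Grp, and 0.74 (SE 0.22) for Sctr. The values were 1.21 for Arid5b, 0.94 for Srrm2, 0.76 for Mga and 0.40 for Camsap2. None of these passed in the fit of all arrays with the array set term, whereas a limma fit of those 7 arrays alone called 30 probe sets higher and 52 lower (3842 at an unadjusted p under 0.05), 4 of them shared with the calls from all arrays, with Vgf (adjusted p = 0.0156), Bdnf (adjusted p = 0.0196) and Cartpt (adjusted p = 0.0376) past the threshold. Bpifa1 (adjusted p = 0.0627), Arid5b, Grp, Camsap2 (adjusted p = 0.0776 for both), Srrm2, Sctr and Mga did not pass in it. The rule for naming required every water-deprived array to lie above the food-deprived mean, so these genes had to be higher within the high set. The 7 arrays were also among those that selected the genes, so the high set alone gives no independent support. Lower in water deprivation were 4 probe sets, chosen for naming after their values were seen: 1 of the differentiation gene Id4 (-1.63, SE 0.30, adjusted p = 0.0481), 1 shared by several symbols (-0.62) and 2 without a symbol (-0.89 and -0.85). Of the genes by their representative probe set none was lower, and the 5 with the smallest unadjusted p were Zc3h3 (-0.48, adjusted p = 0.0506), the growth factor gene Ptn (-0.87), Tmem255a (-0.63), Pals2 (-0.46) and Gnpat (-0.42).

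The lists of glial markers leaned lower in water than in food deprivation. All 22 oligodendrocyte markers lay below 0 (median -0.67, adjusted p = 1.15e-06; adjusted p = 0.644 with an estimated correlation), such as Gal3st1 (-0.86), Cnp (-0.76) and Cldn11 (-0.68). Microglia markers lay below 0 in 21 of 23 (median -0.23, adjusted p = 8.78e-06; adjusted p = 0.573 with an estimated correlation), such as Laptm5 (-0.60), Cx3cr1 (-0.57) and Itgb2 (-0.48), and 3 passed when adjusted over the list alone. Astrocyte markers lay below 0 in 17 of 22 (adjusted p = 0.0286; 0.670 with an estimated correlation), such as Mlc1 (-0.52) and Aqp4 (-0.31), and oligodendrocyte precursor markers in 8 of 9 (adjusted p = 0.0301; 0.573 with an estimated correlation), such as Vcan (-0.45, other probe sets 0.35 and 0.12) and Cacng4 (-0.32). No member of these 4 lists passed over all genes in limma. Within the high set the medians were -0.44, -0.35, -0.26 and -0.37, with adjusted p values of 0.0616, 0.00476, 0.00701 and 0.0616 (each 0.746 with an estimated correlation). This shift is not particular to glia, since neuron markers lay below 0 in 27 of 32 (median -0.27, adjusted p = 0.122), choroid plexus markers above 0 in 25 of 26 (median 0.77, adjusted p = 0.00476) and ependymal markers in 13 of 15 (median 0.23, adjusted p = 0.0616). With an estimated correlation these had an adjusted p = 0.783, 0.746 and 0.746.

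Cell division genes lay below 0 in 18 of 23 (median -0.18, adjusted p = 0.0149; adjusted p = 0.573 with an estimated correlation), with Ccnd1 at -0.38 and past the test only when adjusted over the list alone, and Cenpf at -0.51. Within the high set their median was 0.05. Ribosomal protein genes lay below 0 in 37 of 44 (median -0.12, adjusted p = 0.00161; adjusted p = 0.720 with an estimated correlation), and within the high set their median was 0.03. Oxidative phosphorylation genes lay above 0 in 62 of 76 (median 0.12, adjusted p = 2.27e-07; adjusted p = 0.670 with an estimated correlation), with Atp5mk at 0.42 and Ndufb6 at 0.44 but Cox5a at -0.68, and 3 higher and 1 lower when adjusted over the list alone. Within the high set 70 of 76 lay above 0 (median 0.29, adjusted p = 1.4e-22; adjusted p = 0.746 with an estimated correlation), beside the choroid plexus, ependymal and neuron shifts of that fit (0.77, 0.23 and -0.27).

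Of the appetite and energy balance genes 3 rose in water against food deprivation (Bdnf, Cartpt and Grp), and 4 were higher and 1 lower when adjusted over the list alone, while the list did not pass (adjusted p = 0.333; median -0.03, mean 0.16). Casr was at 1.16 (adjusted p = 0.0597), Fxyd2 at 1.14 (adjusted p = 0.0506), Avp at 2.49 (SE 0.69, adjusted p = 0.112), Oxt at 2.37 (SE 0.71, adjusted p = 0.128), Agtr1a at 0.68 and Fos at 0.66 (adjusted p = 0.129). Within the high set Avp was at 0.67 (SE 0.61), Oxt at 0.56 (SE 0.64), Fos at 0.32 (SE 0.23) and Agtr1a at -0.048. In limma 29 probe sets (11 genes) were higher and 4 lower, with 3427 at an unadjusted p under 0.05, and with the array set as a term 0 and 0, with 2174 (30 and 52 in the fit of the high set alone). Calls fell to 0 higher and 0 lower without food-deprived array 1, 2 or 4 or water-deprived array 3, 4 or 5, to 2 and 0 without food-deprived array 3 or control 1 and to 16 and 1 without control 3. They rose to 269 and 502 without water-deprived array 1, 222 and 313 without water-deprived array 2, 90 and 5 without food-deprived array 5, 44 and 7 without control 4 and 38 and 13 without control 5.

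Any difference among the 3 groups was found for 773 probe sets by the moderated F test of limma (4663 at an unadjusted p under 0.05), and for 7 with the array set as a term. The deprivations share their controls, which alone makes their differences from control alike. No probe set was called in the same direction in both, against 0.0477 expected by chance for higher and 0 for lower ones, and 0 on average in 100 simulations of unchanged groups with shared controls. The covariance of the log2 differences was 0.0472 against a simulated 0.0198. The log2 differences had the same sign in 72.0% of probe sets against a simulated 66.7%, with a correlation across probe sets of 0.637. With the array set as a term the covariance was 0.0444, but that fit was not simulated. In it the difference between food deprivation and control includes that between the low water-deprived arrays and control, which alone makes the differences alike. The simulation models the shared controls and not the array sets, in which 2 of the 5 water-deprived arrays stand with all food-deprived arrays. With the controls divided between the comparisons the covariance was 0.0164 (controls 1 and 2 for water) and 0.0260 (controls 1 and 2 for food), with correlations of 0.133 and 0.281 and an overlap of 0 in both. Bpifa1, the gene called in water deprivation, was not called in food deprivation.

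Control organs gave signal above the filter for transcripts known from the organ and its glia. Mean deposited signals over the 5 controls, which cannot be ranked between probe sets, were 521 (SD 247) for angiotensinogen (Agt), 202 (SD 58.9) for Calcr, 176 (SD 88.0) for Agtr1a, 79.5 (SD 26.4) for Npr1, 50.3 (SD 17.0) for Casr, 70.9 (SD 65.1) for Lepr and 22.7 (SD 4.39) for Ghsr. Those of glial and choroid plexus markers were 1814 (SD 388) for Gfap, 2182 (SD 426) for Aqp4 and 3444 (SD 329) for Ttr. Avp (623, SD 521) and Oxt (1011, SD 759) varied between controls by nearly as much as their means.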

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

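Tests chosen only after the result was seen are the division of the arrays at a 5′/3′ ratio of -1, the slope of the food deprivation differences, the wrong label, the RNA quality test of the water deprivation genes and the comparison of Avp, Oxt and Pmch within the high array set.

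The 1854 probe sets called between food deprivation and control follow the array sets. Of these calls, 93.6% (91.4% to 94.3% with each water-deprived array left out) had the same direction between water-deprived arrays of the high and the low set. This was predicted for a difference in RNA quality, but any other difference between the sets, such as processing or dissection, would give the same. With the 5′/3′ ratio itself as a covariate, 48 probe sets were still higher and 91 lower in limma. The tables argue against food deprivation as the whole source. The differences with the array set as a term had a slope of 0.268 on those without it (0.229 to 0.326 with each array left out), where simulated data with no effect of the set gave 1.00. The slope restates the shared direction and is no further test. The term subtracts from each food deprivation difference the one between the high and the low water-deprived arrays. Without an effect of the set, a slope near 1.00 is thus built in. The tables also argue against a wrong label on water-deprived arrays 1 and 2. These exceeded food deprivation by a median of 0.535 (0.505 to 0.641 with each array of the high set left out) over the 5 genes called with the array set as a term, 4 of them by more than 2 SE. By the rule set beforehand the splits argue against chance, since none of the other splits of the 10 arrays among the 100 drawn gave more than 5 calls. However, the real split is also the split by array set, and every other split mixes the sets. Between water deprivation and control a split that mixed the groups gave 2629 calls, so chance is not excluded for the count. What is left with the term is free of a set effect that acts alike in every group, and limma called 0 probe sets there (1879 at an unadjusted p under 0.05). A set effect that differs between the groups was not tested, because no set holds both.

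Vgf, Casr, Bpifa1, Fxyd2 and Ercc1, higher in water deprivation with the array set as a term, are the second pattern. The term compares arrays of the low set only, which removes a set effect that acts alike in every group. Within the high set 4 of the genes were also higher in water than in food deprivation (median over the 5 genes 0.535, 0.505 to 0.641 with each array of that set left out). Ercc1 was not (0.05, SE 0.12). In limma with the term none passed there (adjusted p = 0.324 for Vgf, 0.447 for Casr, 0.236 for Bpifa1 and 0.404 for Fxyd2). Controls play no part there, and lower values in food deprivation would give the same, so this comparison cannot decide on RNA quality. A dissection that took in more of the organ and less neighbouring tissue stays open. The 3 other organ genes measured had a median of 0.134, under the bound of 0.503 derived from the median of 1.01 of Casr, Calcr (0.22 by another probe set) and Npr1, but ranged from 0.107 (Scn7a) over Lepr to 1.23 (Agtr1a). With 1 array left out Lepr, which gives the median, ranged from -0.22 to 0.56, Scn7a from -0.10 to 0.31 and Agtr1a from 0.91 to 1.43. The calls end in a limma fit of the low arrays alone (adjusted p = 0.307), where the log2 differences are the same and the residual degrees of freedom fall from 11 to 6. The SE is also larger there for Vgf (1.89, SE 0.29 in place of 0.24), Fxyd2 (0.18 in place of 0.16) and Ercc1 (0.12 in place of 0.11), but not for Bpifa1 (0.14 in both). The calls thus rest in part on the spread of the high arrays. In the low arrays alone 782 probe sets had an unadjusted p under 0.05, against 1086 expected by chance. Without water-deprived array 3, which has the lowest 5′/3′ ratio, they end with Vgf at 1.65 (SE 0.24, adjusted p = 0.0930) and Casr at 1.46 (SE 0.23 in place of 0.20, adjusted p = 0.107). Water deprivation itself may account for Vgf, Casr, Bpifa1 and Fxyd2, but the open dissection and RNA quality keep this from being called biological.

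Avp, Oxt and Pmch fell by 3.14, 3.12 and 2.46 on the log2 scale in food deprivation against control, and water-deprived arrays of the high set differed from those of the low set by -3.03, -3.02 and -2.37. Food deprivation as the whole source is argued against, since water minus food deprivation within the high set had a median of 0.558, and its value plus 2 SE (1.88, 1.84 and 1.48) stays under the size of each fall. RNA from hypothalamic tissue, where these genes are strongly expressed, may have entered the low arrays: 12 of 14 transcripts listed beforehand were measured, 11 were higher in the low water-deprived arrays, and their median was 0.362 (0.279 to 0.568 with each water-deprived array left out), with Dlk1 at 1.23, Hap1 at 1.10 and Sst at 1.03. Hcrt, which like Pmch is made in the lateral hypothalamus, goes against it at 0.14 (control mean log2 7.26). This stays open, because the transcripts differ so widely, 6 of the 12 are under the filter, 5 are also in another list, and the abundant Resp18 (control mean log2 10.39, difference 0.37) has a baseline that would hide a small share. No other biological explanation was tested.

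For water deprivation against control 11 of the 100 splits, the real one included, gave at least as many calls as the real 1, so chance cannot be excluded for that count. The highest other split, with water-deprived arrays 1, 2 and 5 and controls 3 and 5 together, gave 2629 calls, which points to a structure of the samples. For water against food deprivation 2 of the 100 splits, the real one included, gave at least as many calls as the real 33. By the rule set beforehand this argues against chance. However, the highest other split gave 71 and put food-deprived arrays 1 and 2 with water-deprived arrays 3 to 5. A limma fit of only the 10 arrays compared called 0, so chance is not excluded for that count.

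Of 393 groups of 5 arrays tested, 18 had 1 array whose gap to its nearest neighbour exceeded 0.71 of the range of the group. Chance marks about 1 in 20 groups, or 19.65 of these. In controls the share of the range was 0.895 for Gabrg1 (control 1 highest), 0.858 for Calcr (control 4 highest), 0.850 for G0s2 (control 5 lowest) and 0.802 for Ghsr (control 5 highest). In food deprivation it was 0.923 for G0s2 and 0.813 for Cldn11 (array 1 lowest in both), 0.753 for Dusp1 (array 1 highest), 0.929 for Slc6a6 (array 2 lowest), 0.718 for Strbp (array 2 highest), 0.802 for Pmch (array 3 lowest), 0.796 for Rlig1 (array 3 highest), 0.744 for Scg2 (array 3 lowest) and 0.757 for Elovl6 (array 5 highest). In water deprivation it was 0.824 for Galr2 (array 1 highest), 0.895 for Sgk1 (array 3 lowest), 0.817 for Fkbp5 and 0.714 for Egr1 (array 3 highest in both) and 0.773 for Psmc3 (array 5 lowest).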

How the results depend on the processing

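The settings with the array set, the 5′/3′ ratio or the arrays of 1 set were chosen after seeing the data, and the others were planned. Counts are given as higher and lower probe sets, and except where stated the cause of a change was not tested. A variance without a trend left every count within 1.5 times its value. Quantile normalization gave 87 and 19 between water and food deprivation, and median centring 652 higher between food deprivation and control and 94 and 7 between water and food deprivation. Between water and food deprivation an offset of 1 gave 2 lower and an offset of 64 gave 18 higher. Without a filter there were 2 and 1 between water deprivation and control, 17 higher between water and food deprivation and an overlap of 1 between the deprivations. With the filter at the 50th percentile, where fewer probe sets are tested, there were 0 higher between water deprivation and control, 534 higher between food deprivation and control, 57 and 14 between water and food deprivation and 486 in the F test. Array weights gave 1 lower between water deprivation and control, 3458 and 2382 between food deprivation and control, 955 and 1789 between water and food deprivation, 5145 in the F test and an overlap of 1. A fit of the 10 arrays compared gave 0 higher between water deprivation and control, 2567 and 1616 between food deprivation and control and 0 and 0 between water and food deprivation. A minimum of 1.5-fold left 610 higher between food deprivation and control.

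The replicate numbers gave no sign of pairing: correlations within the 15 pairs of the same number, after removal of group means, ranged from -0.36 to 0.37, with 3 over 0.1, and 1 of 15 arrays correlated best with an array of its own number. Correlations between unlike numbers reached -0.61 and 0.56. The array sets were not removed and could hide a pairing, so these values cannot exclude one. With the replicate number as a block there were 0 higher between water deprivation and control, 687 higher between food deprivation and control, 19 and 1 between water and food deprivation and 397 in the F test. With the array set and the block there were 0 higher between water deprivation and control, 0 and 0 in both comparisons with food deprivation and 3 in the F test.

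With the array set as a term, and also with quantile normalization added to it, there were 6 higher between water deprivation and control, 0 and 0 in both comparisons with food deprivation and 7 in the F test. With the term and without water-deprived array 3 all of these were 0. With the 5′/3′ ratio as a covariate there were 2 lower between water deprivation and control, 48 and 91 between food deprivation and control, 0 and 0 between water and food deprivation, 27 in the F test and an overlap of 1. The arrays of the low set alone gave 0 higher between water deprivation and control, and those of the high set alone 30 higher and 52 lower between water and food deprivation, 4 of them shared with the calls from all arrays. Each 0 here is from limma, and the unadjusted counts with the term are 1295, 1879 and 2174 for the 3 comparisons.

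Leaving out 1 array at a time, with or without the array set as a term, gave 0 to 12 higher and 0 to 7 lower between water deprivation and control, 0 to 1715 higher and 0 to 1139 lower between food deprivation and control, 0 to 269 higher and 0 to 502 lower between water and food deprivation, 0 to 1477 in the F test and an overlap of 0 to 1. Without the term the lowest counts between food deprivation and control were 398 and 409, both without control 1, and the highest 1715 and 1139, both without water-deprived array 3. The F test had 211 without food-deprived array 3 and 1477 without water-deprived array 1.

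Over the settings fixed in advance, 4580 values of named genes and 2208 of lists had the same direction and side of the threshold, 382 and 61 lost their call and 112 and 50 gained one. Over the settings chosen after seeing the data these numbers were 387 and 275, 193 and 26, and 6 and 38. A further 61 and 110 values under the former and 99 and 61 under the latter changed direction without a call under either setting. Some log2 differences between food deprivation and control turned direction. Those with the array set as a term were -0.060 for Rps27l, -0.27 for Rlig1, -0.10 for Tmem158, -0.14 for Strbp, 0.080 for Gnai2, 0.29 for Atp1b2, -0.046 for Ccn3, -0.10 for Psmc6 and -0.34 for Adipor2. With the term and without water-deprived array 3 they were -0.054 for Rps27l, -0.25 for Rlig1, -0.050 for Tmem158, -0.17 for Strbp, -0.030 for Sstr3, 0.12 for Atp1b2, -0.0040 for Scn4b, 0.086 for Calr, 0.072 for Sparc, -0.041 for Ccn3, -0.0041 for Rps9, -0.035 for Rpl5 and -0.15 for Psmc6. The list medians that turned with the term were 0.34 for glutamate and GABA receptors, -0.16 for cell division, 0.44 for neuron markers, -0.012 for oligodendrocyte markers, -0.88 for choroid plexus markers, -0.026 for ribosomal proteins and -0.25 for oxidative phosphorylation. With the covariate they were 0.23 for glutamate and GABA receptors, 0.21 for neuron markers and -0.56 for choroid plexus markers. With the term and without water-deprived array 3, ribosomal proteins were at -0.036 in water deprivation against control and -0.089 in food deprivation against control, and oxidative phosphorylation at -0.20 in the latter. Between water and food deprivation ribosomal proteins turned to 0.031 with the term (with or without water-deprived array 3) and in the high set alone, where neuron markers were at -0.27. With 1 array left out at a time, neuron markers in water deprivation against control ranged from -0.18 (without control 5) to 0.13 (without control 2). An estimated correlation changes no median, and the same medians of -0.012, -0.026 and 0.031 apply to it. The offset of 16 is near the 25th percentile of the signal. With offsets of 1 and 64, 191 and 195 values of named genes kept their direction and side of the threshold.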

Other observations

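The tests with the array set as a term were chosen after seeing the data. Without that term, other gene groups of the organ and its surroundings did not pass against control. Choroid plexus markers had medians of 0.42 in water and 0.44 in food deprivation against control (adjusted p = 0.0805 and 0.482), septal, hippocampal and thalamic neuron markers 0.12 and 0.20 (adjusted p = 0.592 and 0.482), and endothelial markers 0.09 and 0.12 (adjusted p = 0.103 and 0.13). Ependymal markers were at -0.01 and 0.04, mural cell markers at -0.02 and 0.13 and meningeal markers at -0.04 and -0.02. Neuron markers were at -0.01 and 0.01, potassium, calcium and HCN channels at 0.02 and 0.06, sodium channels and pumps at -0.00016 and 0.14, and glutamate and GABA receptors at -0.0022 and 0.05. Hypertonicity response genes were at 0.05 and 0.08, heat shock genes at -0.07 and -0.08, chaperone genes at 0.03 and 0.01, clock genes at -0.06 and -0.04, fasting and fatty acid genes at -0.03 and 0.0021, inflammation genes at 0.03 and 0.09 and interferon genes at -0.02 and 0.07. None of these lists passed in any of the 3 comparisons without the term. The erythrocyte list had 4 measured members and was not tested.

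For several of these lists the test, the mean and the median differ in sign. Against control in water deprivation the means were 0.01 for sodium channels and pumps, 0.0013 for glutamate and GABA receptors, 0.01 for fasting genes, 0.07 for neuron markers and 0.01 for ependymal markers, and the test of inflammation genes pointed down while mean and median were above 0. In food deprivation the means were -0.18 for fluid balance signalling (median 0.08), -0.0059 for glutamate and GABA receptors, -0.04 for chaperones, -0.05 for neuron markers and -0.04 for ependymal markers. Between water and food deprivation the medians and means were -0.03 and 0.24 for fluid balance signalling, -0.03 and 0.01 for glutamate and GABA receptors, -0.0027 and 0.12 for neuron markers and -0.17 and 0.0034 for septal, hippocampal and thalamic neuron markers. Adding the array set term gave a mean of -0.0092 for ribosomal proteins in water deprivation against control (median 0.016) and of 0.012 for oligodendrocyte markers in food deprivation against control (median -0.012). Cell division genes between water and food deprivation then had a mean of -0.029 (median 0.051).

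With the array set as a term, 11 lists moved between food deprivation and control by the preset correlation and 0 with an estimated one, the smallest adjusted p being 0.365. Neuron markers had an adjusted p = 0.000263, choroid plexus markers an adjusted p = 0.0113, ependymal markers a median of -0.31 (adjusted p = 0.0264) and oxidative phosphorylation -0.25 (adjusted p = 8.86e-10). Between water deprivation and control cell division genes were at -0.15 (adjusted p = 0.000123; 0.0486 with an estimated correlation), beside oligodendrocyte markers at -0.33, microglia markers at -0.24 and neuron markers at 0.16, and they did not pass without the term (adjusted p = 0.0978).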
